A study of Mus musculus with 4 samples.

How the data were processed

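RNA was taken from the ureter of 4 male mice, 2 wild type and 2 with deletion of the miR-143 and miR-145 genes, and 500 ng of total RNA per mouse was labelled for an Affymetrix whole-transcript mouse array, per the labels' protocols. The values are the log2 expression values that the authors deposited, 1 per probe set and array; RMA, R 2.15.0 and limma 3.12.1 are named in the submitters' processing notes. RMA corrects background, makes the distributions of the arrays alike and summarises the probes of a set on the log2 scale, so a change shared by most genes would be reduced. The genome build behind the probe sets is not given in the sources used here, and no coordinates are printed; the gene table of assembly GRCm38.p6 served only for names and for which genes neighbour each other.

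The table held 23309 probe sets. The platform annotation gave 1 symbol to 20728 of them, several to 1174 and none to 1407, and no gene was named from the last 2 kinds, which may hold control probe sets. Of those with 1 symbol, 20685 matched the gene table by Entrez ID and 0 symbols needed an update. For the 804 genes with over 1 probe set the brightest over all arrays was used, which left 19296 genes, with no filter on dim genes. The background level was the 95th percentile of the mean values of 1024 olfactory receptor genes, log2 6.58, and 14227 genes lay above it in at least 1 genotype. Where a genotype lay below it on both arrays, the fold is given as a bound, the brighter mean against, per array, the higher of the background level and the measured value. For arrays no counting depth exists, and the precision is set by 2 mice per genotype.

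Knockout was compared with wild type by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with no intensity trend and not robust), with Benjamini-Hochberg adjustment over all genes and an adjusted p threshold of 0.05. Every adjusted p of a single gene comes from this fit, and SE is its moderated standard error. The labels describe the 2 mice of a genotype as biological replicates. Age and kidney state follow genotype completely, so neither entered the fit. The 20 gene lists, 10 on the biology of the ureter wall and 10 on other cell types, handling or linkage, were fixed before the data were examined, as was the rule for naming genes. The lists are smooth muscle contractile genes, calcium handling and ion channels, reported miR-143 and miR-145 targets, extracellular matrix and fibrosis, urothelium, macrophages and antigen presentation, cytokines and acute inflammation, cell cycle, ureter mesenchyme with hedgehog and BMP signalling, the renin-angiotensin system, lymphocytes, endothelium, kidney parenchyma, adipocytes, male accessory glands, skeletal muscle, peripheral nerve and glia, immediate early and heat shock genes, interferon response and neighbours of the cluster. Of their 544 genes 504 were tested. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 20 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way without a comparison to other genes, were alternatives; with the estimated correlation no list kept its call.

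Named genes are Mir143 and Mir145a, the 12 largest rises and 12 largest falls, ranked by the measured difference even where only a bound is printed, among genes past the threshold with genotypes that do not overlap, the 4 members of smallest p in each list on the ureter wall and the 2 of smallest p in each other list, among those above background in at least 1 genotype. On simulated data for this comparison with 19296 genes, limma recovered 74.2% of genes changed by 1 on the log2 scale. It recovered 99.8% of those changed by 2 and 2.16% of those changed by 0.5, and 5.53% of calls were false. Each run changed 200 genes, drew variances from the prior that limma had fitted and used noise independent between genes. The rates thus hold under the model of limma itself and need not carry over to arrays whose genes vary together. Alternatives were a replicate block, a filter on dim genes, a further quantile normalization, centring on array medians, the mean of a gene's probe sets, all probe sets, an intensity trend, robust eBayes, array weights, no pooling of the variance, other thresholds and leaving out each mouse in turn. The mean of the kidney list as a covariate was added after seeing the data. A test of genes with seed matches of the microRNAs was left out, since no transcript sequences were used here.

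For the closing observations, values were compared with bounds written down beforehand where stated. For 2 tests chosen after their results were seen, that of other tissues rising alike and that of the Hoxc genes, the bound was first 2 standard errors and was raised to 4.30, the 0.975 quantile for 2 degrees of freedom, after both values were known, because a spread from 2 mice per genotype needs the wider bound.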

Results

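Gene expression was measured in the ureter of male mice of a mixed 129Sv and C57BL6 background that carried or lacked the genes for the microRNAs miR-143 and miR-145. These small RNAs are made from 1 shared cluster and are abundant in smooth muscle, the contractile layer that moves urine along the ureter. There were 2 wild type and 2 knockout mice, with 1 array per mouse. The wild type mice were 4.5 months old with normal kidneys, and the knockout mice were 2.5 months old with hydronephrosis, a swelling of the kidney from retained urine. Genotype, age and kidney state therefore changed together, and each difference below is a difference between these groups of mice. The median log2 value of the arrays lay between 7.81 and 7.89. Of 19296 genes, 13838 and 14231 lay above a background level of log2 6.58 on the wild type arrays, and 13515 and 13558 on the knockout arrays. The lower quartile of the probe sets was 6.36 and 6.45 in wild type and 6.26 and 6.27 in knockout. Dim genes may therefore read lower in knockout, whatever they encode. Across genes, the correlation was 0.993 between the wild type arrays, 0.991 between the knockout arrays, and 0.980 to 0.985 between genotypes; genes are not independent replicates. The number of arrays limits the precision of every value.

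The deleted genes were checked first. Mir145a (probe set 10459225) measured 8.35 ± 0.09 (SD, n = 2) in wild type and 4.81 ± 0.30 (SD, n = 2) in knockout ureter on the log2 scale. Both knockout values lay below background, so the fall was at least 3.42-fold (limma, adjusted p = 0.00193). Mir143 (probe set 10459227) measured 7.74 ± 0.15 in wild type and 6.51 ± 0.03 in knockout ureter (SD, n = 2 each). Its knockout values were also below background, and it was at least 2.24-fold lower (limma, adjusted p = 0.0148). These bounds set the wild type mean against the background level. Of the 28 tested neighbours of the cluster on its chromosome, 14 were higher and 14 lower, with a median log2 difference of -0.00 (camera adjusted p = 0.789). Among them Sh3tc2 rose by 0.90 (SE 0.14, adjusted p = 0.0363), while Slc26a2, a sulfate transporter, differed by 0.50 (adjusted p = 0.0658). Adjusted over the list alone, 2 neighbours were higher; without knockout replicate 1, 2 were higher and 2 lower over all genes. The call of Sh3tc2 was lost with a further quantile normalization (adjusted p = 0.0532).

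In the comparison of all 4 mice, the lists of the extracellular matrix and of ureter mesenchyme held the most genes that rose in knockout ureter, 12 and 9. The largest rise was that of Adam28, a membrane-bound metalloprotease, at 5.01-fold. Mfap4, a protein of elastic fibres, rose 4.77-fold, and heparanase, encoded by Hpse, rose 4.72-fold. Among genes past the threshold and above background in both genotypes, the largest fall was that of Cyp2b10, a cytochrome P450 gene. In total 459 of 19296 genes passed an adjusted p of 0.05, of which 367 were higher and 92 lower in knockout. With the arrays centred on their medians, 309 were higher and 317 lower, so the excess of rises depended on the scaling; this centring moved the median difference of all genes from -0.02 to -0.10. A difference of at least 1 on the log2 scale was met by 101 of the higher and 29 of the lower genes. The 2 mice of one genotype lay wholly above those of the other for 11579 of 19296 genes. Over the 3 splits of the arrays into pairs the average share is 33.3%. All genes share the same 4 arrays, so an array-wide difference can raise the share of 1 split, and the count does not measure chance.

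C1qtnf3 rose by log2 2.23 (SE 0.25, adjusted p = 0.0197) and Lgr5, a receptor for R-spondins, by 1.91 (SE 0.28, adjusted p = 0.0328). Eno3, the muscle form of enolase, rose by 2.08 and Armh4 by 1.90, both at adjusted p = 0.0111. The vasopressin receptor gene Avpr1a rose from 9.19 ± 0.31 to 10.98 ± 0.10, and the matrix glycoprotein gene Tnc from 9.50 ± 0.26 to 11.33 ± 0.16 (SD, n = 2 each), both at a limma adjusted p of 0.0147. Bmp5, Adamdec1 and Lum completed the 12 largest rises at log2 1.79, 1.72 and 1.70. Among the largest falls, Igkv8-30 was at least 2.55-fold lower (adjusted p = 0.0386) with its knockout values below background. This gene encodes an immunoglobulin light chain segment. Sult1e1, an estrogen sulfotransferase, was at least 1.52-fold lower (adjusted p = 0.0147), with knockout values also below background. Igha, the heavy chain of immunoglobulin A, fell by 1.58 (SE 0.14, adjusted p = 0.0147). Cyp2b10 fell by 2.04 (SE 0.36) and Rasd1 fell by 1.88 (SE 0.31), at adjusted p = 0.0454 and 0.0394. G0s2, an inhibitor of fat breakdown, fell by 1.34. Klb, a co-receptor for fibroblast growth factors, and Coq8a, which acts in coenzyme Q synthesis, fell as well, with log2 differences of -1.29 and -1.28. Tst, B3galt2 and Olfr767 completed the 12 largest falls at -1.44, -1.42 and -1.28. Adipocyte markers were bright on these arrays and lower in knockout, as given below. Whether the largest falls arose in the ureter wall or in fat was not tested. The calls of Bmp5, Igkv8-30, Cyp2b10, Rasd1 and B3galt2 were lost with a further quantile normalization (adjusted p 0.0532 to 0.0629), and the first 4 of them also with robust eBayes (0.0628 to 0.156); that of B3galt2 was lost with array weights too (0.0515).

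**Figure D1:**
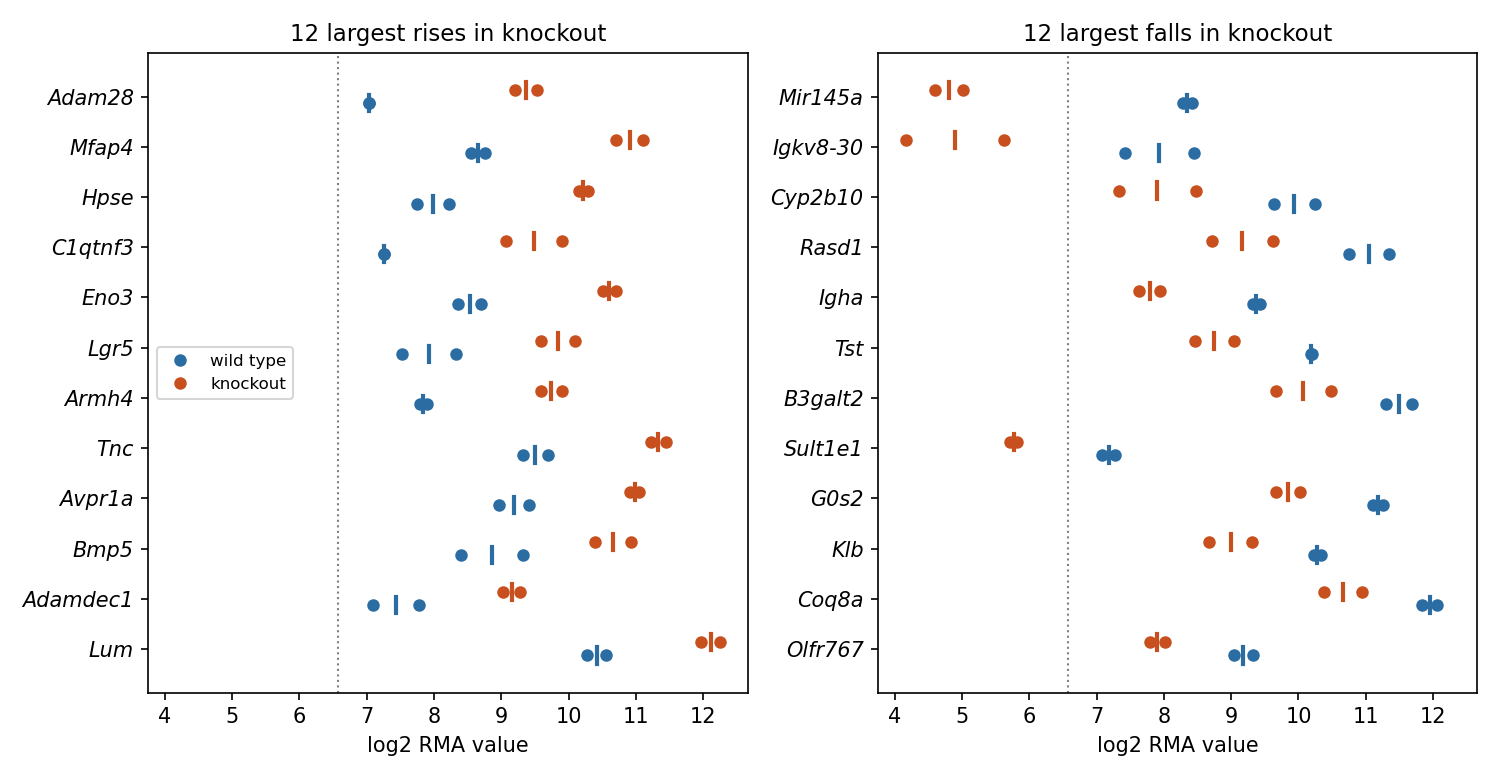
Log2 values on the horizontal axis of the 12 genes with the largest rise and the 12 with the largest fall in knockout, with 1 point per mouse, a bar at each genotype mean and a dotted line at the background level of 6.58. The 2 mice of each genotype lie apart from the other genotype for every gene drawn, and the knockout values of Mir145a, Igkv8-30 and Sult1e1 lie below background.

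Of 36 tested genes of the extracellular matrix, 12 rose and 24 did not pass, with a median log2 difference of 0.35; adjusted over the list alone, 17 were higher. Mfap4 rose from 8.65 ± 0.15 to 10.91 ± 0.28 and Col12a1, a fibril-associated collagen, from 9.36 ± 0.02 to 10.56 ± 0.00 (SD, n = 2 each). Tnc and Lum, the latter a proteoglycan of collagen fibrils, were the other named members. The list was shifted upward against all other genes (camera adjusted p = 1.02e-09), which was lost at adjusted p = 0.894 with an estimated correlation. With a further quantile normalization 7 members rose.

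The list of ureter mesenchyme, hedgehog and bone morphogenetic protein signalling held 34 tested genes, of which 9 rose and 25 did not pass. Hhip, a hedgehog-binding inhibitor that is itself induced by hedgehog signalling, rose by 1.62 (SE 0.19, adjusted p = 0.0208). Bmp2 rose by 1.01 (adjusted p = 0.0394), Tbx18, a transcription factor of ureter mesenchyme, by 0.80 (adjusted p = 0.0368), and Aldh1a1, a retinoic acid synthesis enzyme, by 0.78 (adjusted p = 0.0353). The median was 0.41, and 19 genes were higher and 1 lower when adjusted over the list alone. The upward shift of the list (camera adjusted p = 1.89e-10) was lost at adjusted p = 0.894 with an estimated correlation. Without knockout replicate 1, 15 of its genes passed and were higher, while with a further quantile normalization 1 did. That setting ended the calls of Bmp2, Tbx18 and Aldh1a1 (adjusted p = 0.0629, 0.0532 and 0.0532).

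Urothelium, the epithelium that lines the ureter, showed a broad upward difference. Its 32 tested markers had a median difference of 0.64, and 30 were higher in knockout. Over all genes 2 passed: Cldn8, a tight junction protein, rose 2.00-fold (adjusted p = 0.0386), and Trp63, the transcription factor of basal epithelial cells, rose 1.78-fold (adjusted p = 0.0486). Gata3 differed by 0.84 (adjusted p = 0.0566) and Ocln by 0.74 (adjusted p = 0.0517). Adjusted over the list alone, 28 were higher. These markers varied together, with an estimated inter-gene correlation of 0.88, so they do not count as independent. The urothelium list means were 10.44 and 10.72 in wild type and 10.96 and 11.30 in knockout. The list shift had a camera adjusted p of 3.58e-11, and an adjusted p = 0.894 with an estimated correlation. Without knockout replicate 1, 25 of the markers passed over all genes, and without knockout replicate 2, 1 did, with Trp63 at adjusted p = 0.0593. With a further quantile normalization 0 passed, with Cldn8 at adjusted p = 0.0595 and Trp63 at 0.0676.

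Smooth muscle contractile genes were modestly higher. Of 32 tested, 3 rose and 29 did not pass, and adjusted over the list alone 6 were higher; the median difference was 0.25. Myocd, a coactivator that drives smooth muscle genes, rose 2.01-fold (adjusted p = 0.0208), Mustn1 2.01-fold (adjusted p = 0.0453), and the integrin gene Itga8 1.75-fold (adjusted p = 0.0319). Nexn differed by 0.98 (adjusted p = 0.0587). The call of Mustn1 was lost with a further quantile normalization (adjusted p = 0.0628). Filament genes outside the rule for naming were chosen after their values were seen. Acta2 differed by 0.17, Myh11 by 0.35, Des by -0.30 and Synm by -0.54, and none passed. Of all members 28 were higher and 4 lower, with 13 higher and 2 lower at an unadjusted limma p under 0.05. The list was shifted upward (camera adjusted p = 7.17e-06), which was lost at adjusted p = 0.894 with an estimated correlation.

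Genes for calcium handling and ion channels moved in both directions. Of 30 tested, 4 rose and 26 did not pass, and adjusted over the list alone 9 were higher and 4 lower; without knockout replicate 1, 4 were higher and 4 lower over all genes, and without knockout replicate 2, 3 were higher and 2 lower. The ATP-sensitive potassium channel subunit Abcc9 rose by 0.83, the large-conductance potassium channel Kcnma1 by 0.91, Kcnq5 by 0.83 and the calcium channel Cacna1d by 0.66, the last at adjusted p = 0.0499. A second probe set of Kcnma1, below background, differed in sign, and with the mean of both the call was lost (adjusted p = 0.141). That of Cacna1d was lost with a further quantile normalization (adjusted p = 0.0727), with centred arrays (0.0533), with array weights (0.0515) and without knockout replicate 2 (0.0880). The median was 0.09 and the list was not shifted (camera adjusted p = 0.196).

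Genes reported elsewhere as targets of miR-143 or miR-145 were slightly higher as a list. Of 39 tested, Igfbp5, which binds insulin-like growth factors, rose by 0.78 (SE 0.12, adjusted p = 0.0349) and 38 did not pass; adjusted over the list alone, 10 were higher. Over all genes, 6 were higher and 2 lower without knockout replicate 1, and 2 were higher without knockout replicate 2. Vcan, a large matrix proteoglycan, differed by 1.22 (adjusted p = 0.0503), Cd44 by 0.70 (adjusted p = 0.0566) and the growth factor receptor Pdgfra by 0.51 (adjusted p = 0.0658). The median was 0.20 and 31 members were higher. The camera adjusted p was 0.000852, and the adjusted p = 0.894 with an estimated correlation.

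**Figure D2:**
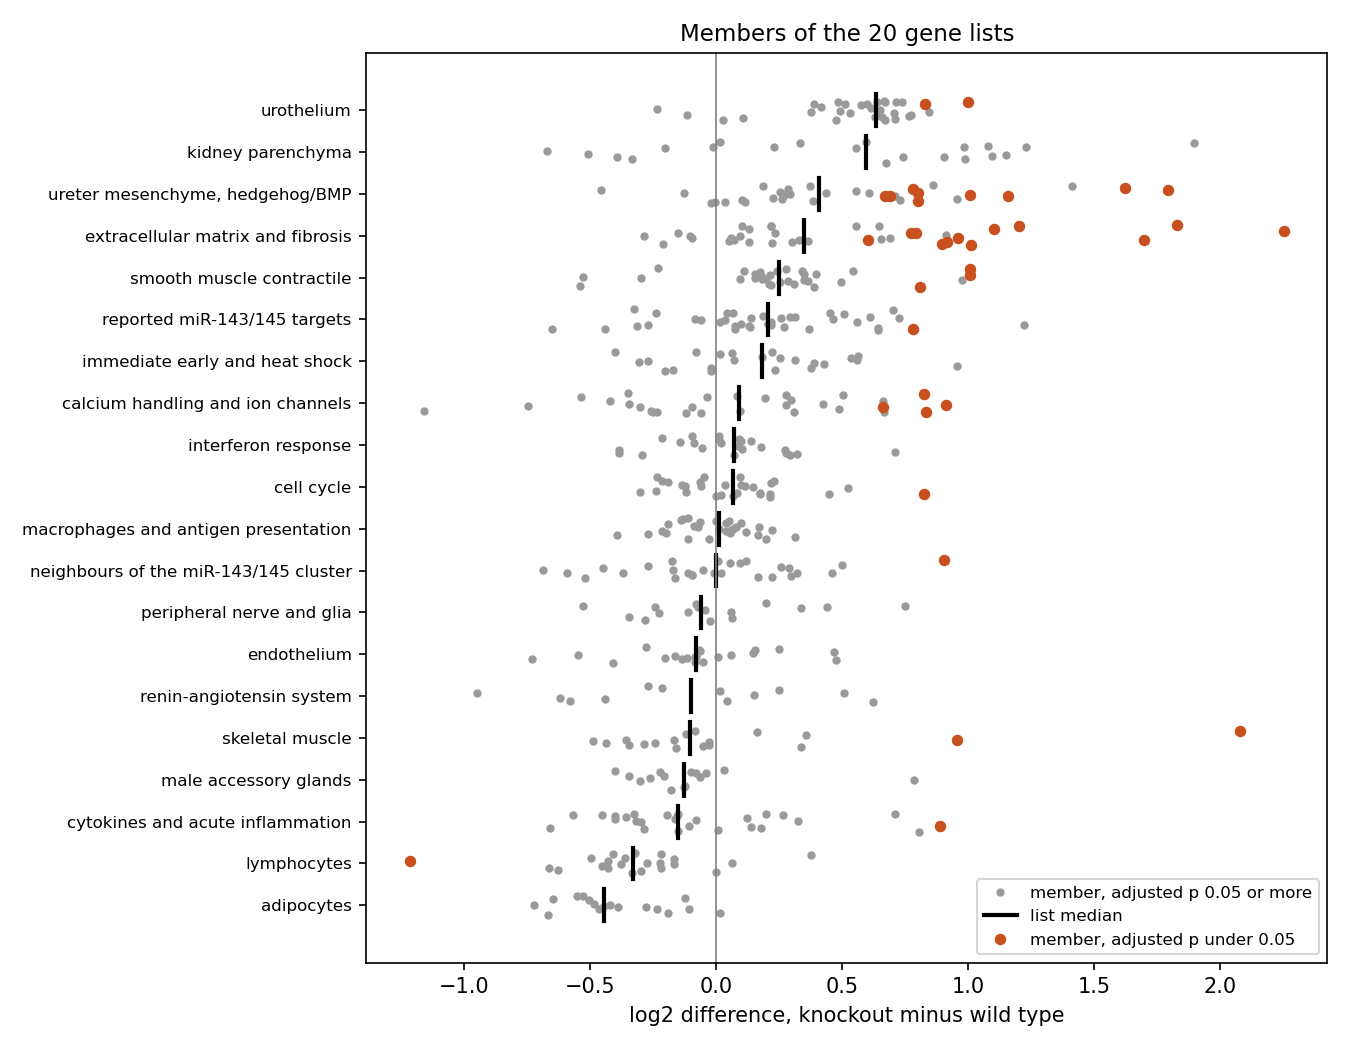
Log2 difference between knockout and wild type (horizontal axis) for each member of the 20 gene lists (vertical axis, with scatter for legibility), with a black bar at the list median and orange points at an adjusted p under 0.05. The medians run from -0.45 for adipocytes to 0.64 for urothelium.

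Markers of lymphocytes and adipocytes were lower beside these rises. Of 22 lymphocyte genes tested, 9 of them above background, Ighm, the heavy chain of immunoglobulin M, fell by 1.22 (SE 0.20, adjusted p = 0.0399) and 21 did not pass. With the mean of its 2 probe sets the call of Ighm was lost (adjusted p = 0.0999). Cd8a, below background in knockout, was at least 1.20-fold lower and did not pass (adjusted p = 0.0954). With knockout replicate 1 or knockout replicate 2 left out, 2 lymphocyte genes were lower. Adjusted over the list alone, 9 were lower and 1 higher, but 7 of the lower genes and the higher one lay below background in both genotypes; the median was -0.33, and the list was shifted downward (camera adjusted p = 9.40e-05; adjusted p = 0.894 with an estimated correlation). Of 17 adipocyte genes, 16 were lower and the median was -0.45, but limma passed 0 of them over all genes or adjusted over the list alone, with 7 lower at an unadjusted p under 0.05. Adipoq differed by -0.73 (adjusted p = 0.0869) and Retn by -0.65 (adjusted p = 0.0904). The adipocyte list means were 12.96 and 12.88 in wild type and 12.74 and 12.30 in knockout. Those of the smooth muscle list were 10.56 and 10.48 in wild type and 10.84 and 10.75 in knockout, so adipocyte markers were bright in these ureter samples. For the adipocyte list the camera adjusted p of 0.000229 became adjusted p = 0.918 with an estimated correlation. Without knockout replicate 1, 10 adipocyte genes passed and were lower; without knockout replicate 2, 0 did and the list shift was lost (adjusted p = 0.0569).

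Kidney markers differed between mice of one genotype. The list means were 6.99 and 7.59 in wild type replicates 1 and 2, and 8.54 and 7.02 in knockout replicates 1 and 2. The 21 tested genes had a median difference of 0.60 (camera adjusted p = 0.394), and limma passed 0, with 2 higher and 2 lower at an unadjusted p under 0.05; adjusted over the list alone the count was also 0. Cubn, the endocytic receptor of the proximal tubule, was below background in wild type and at least 1.75-fold higher in knockout without passing (adjusted p = 0.0762). Cyp2e1 differed by -0.67 (adjusted p = 0.0767). Its values, 13.56 and 13.49 in wild type and 13.09 and 12.61 in knockout, did not follow the kidney list means. Without knockout replicate 1 the list was shifted downward (adjusted p = 0.0181), and without knockout replicate 2 it was shifted upward (adjusted p = 1.16e-13) with 12 genes higher.

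**Figure D3:**
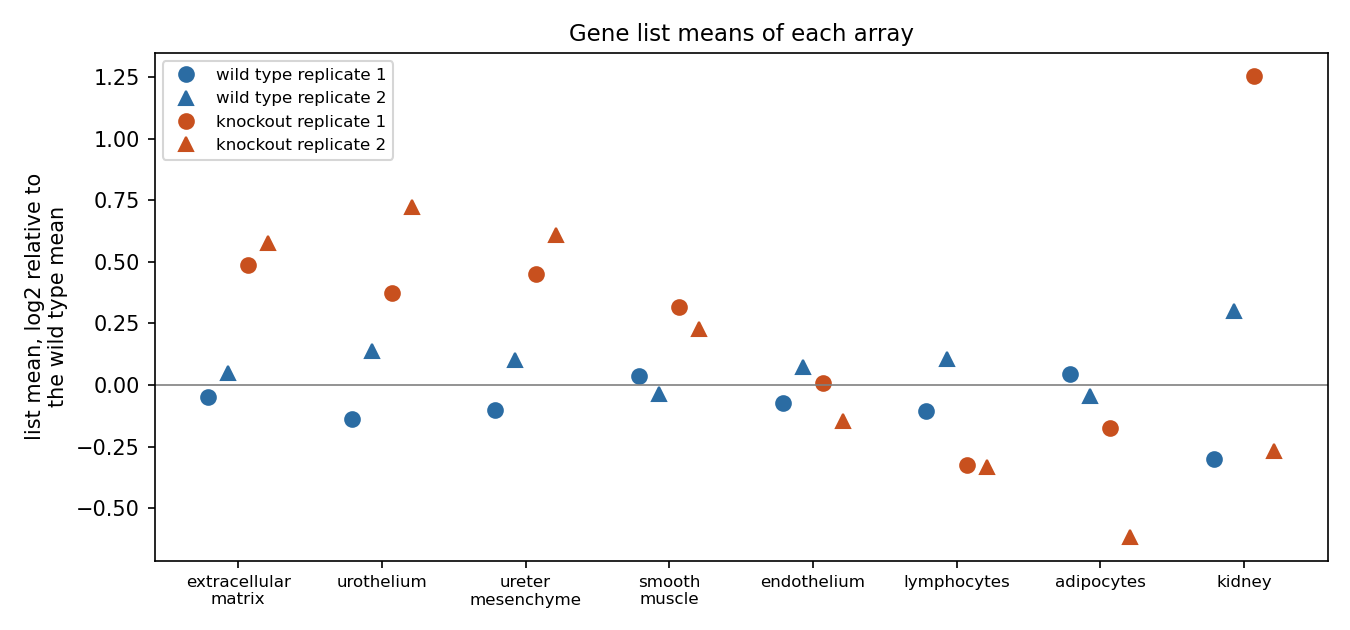
Mean log2 value of 8 gene lists on each of the 4 arrays (vertical axis, relative to the wild type mean of that list), with circles for replicate 1 and triangles for replicate 2. Both knockout arrays lie above both wild type arrays for the matrix, urothelium, mesenchyme and smooth muscle lists, and the kidney list separates knockout replicate 1 from the other arrays.

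The macrophage, cytokine and interferon lists showed no shift. Among 29 macrophage and antigen presentation genes limma passed 0, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone, and the median was 0.01 with a mean of -0.01 (camera adjusted p = 0.987); Lyz2 differed by -0.39, Csf1r by -0.27, Lgals3 by 0.31 and Itgam by 0.22. Of 27 cytokine and acute inflammation genes, Vcam1, an adhesion molecule for leukocytes, rose by 0.89 (SE 0.15, adjusted p = 0.0403) and 26 did not pass; 2 were higher and 1 lower adjusted over the list alone (median -0.15, camera adjusted p = 0.487). Sele differed by 0.81 and Il1rn by -0.66, and Ccl3, below background in knockout, was at least 1.04-fold lower without passing. The call of Vcam1 was lost with a further quantile normalization (adjusted p = 0.0641). With knockout replicate 1 or knockout replicate 2 left out, 2 genes of this list were higher and 1 was lower over all genes. The 23 interferon response genes had a median of 0.07 (camera adjusted p = 0.553). Limma passed 0 of them, with 2 higher and 2 lower at an unadjusted p under 0.05 and 1 higher adjusted over the list alone; Usp18 differed by 0.71 and Oas1a by -0.39. Without knockout replicate 1, 1 interferon response gene was higher over all genes.

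The remaining lists were not shifted in the comparison of all 4 mice. Of 29 cell cycle genes, Mcm6, part of the replicative helicase, rose by 0.83 (SE 0.12, adjusted p = 0.0349) and was the 1 gene higher adjusted over the list alone; Tyms differed by 0.52, Mcm4 by 0.45 and Mcm2 by 0.22 (median 0.07, camera adjusted p = 0.416). Of 12 renin-angiotensin genes limma passed 0, with 2 higher and 4 lower both at an unadjusted p under 0.05 and adjusted over the list alone (median -0.10, camera adjusted p = 0.647). Enpep differed by 0.62, Agtr1a by -0.62 and Agt by -0.95, and Cma1, below background in knockout, was at least 1.01-fold lower without passing. Of 18 skeletal muscle genes Eno3 and Pygm, the muscle glycogen phosphorylase, rose by 2.08 and 0.96, and these 2 also passed adjusted over the list alone, while the median was -0.10 and the mean 0.06 (camera adjusted p = 0.858). Of 21 endothelial genes limma passed 0, with 2 higher and 3 lower at an unadjusted p under 0.05 and 1 higher and 1 lower adjusted over the list alone (median -0.08, camera adjusted p = 0.647); Cldn5 differed by -0.73 and Sox17 by 0.48. Of 16 nerve and glia genes limma passed 0, with 2 higher and 2 lower at an unadjusted p under 0.05 and 1 higher adjusted over the list alone (camera adjusted p = 0.934); Erbb3 differed by 0.75 and Uchl1 by 0.44. Of 23 immediate early and heat shock genes limma passed 0, with 5 higher and 1 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone (median 0.18, camera adjusted p = 0.148); Ier3 differed by 0.56 and Fosl2 by 0.43. This list was shifted upward without wild type replicate 2 (adjusted p = 0.000116) and without knockout replicate 2 (adjusted p = 0.0112), where 2 of its genes were higher over all genes. None of the 15 tested genes of the male accessory glands lay above background (camera adjusted p = 0.172), and limma passed 0, with 3 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. That list was shifted downward without wild type replicate 1 (adjusted p = 0.0148), and 1 of its genes was higher over all genes without knockout replicate 2. Without knockout replicate 1, 1 endothelial gene was higher and 3 were lower, 2 nerve and glia genes and 2 cell cycle genes were higher, and 1 renin-angiotensin gene was higher and 2 were lower. The medians of the macrophage, cell cycle and interferon lists changed sign when arrays were centred on their medians, and that of nerve and glia when they were quantile normalized once more.

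Without wild type replicate 1 or wild type replicate 2, limma passed 0 genes, with 4253 and 3079 at an unadjusted p under 0.05, and without knockout replicate 1 it passed 1744. With 2 mice per genotype the smallest two-sided p of an exact permutation test is 0.333, so every call rests on the variance that limma pools across genes; without that pooling 0 genes passed and 2580 had an unadjusted p under 0.05.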

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

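Of the settings given here, the kidney list mean as a covariate was chosen only after the result was seen. Of 79 named genes 0 changed direction under any setting that refitted them, but 45 lost their call without either wild type mouse and 14 with a further quantile normalization. Most named genes were chosen for genotypes that lie apart or for the smallest p. A change of direction was therefore unlikely from the start, and its absence is no evidence of stability. The count of 459 genes became 214 with a further quantile normalization, 902 with robust eBayes, 2299 at an adjusted p of 0.1, 130 with a log2 difference of at least 1, 117 over all probe sets, 0 with no pooled variance and 1969 with the covariate. Leaving out 1 mouse gave 0 to 1744 genes, where the lone mouse is assumed to vary like the other genotype; the prior degrees of freedom were 3.47 without a wild type and 11.9 without a knockout mouse, against 5.03. The replicate numbers were not taken to pair the mice (correlation of deviations -0.03); with them as a block 1922 genes passed. With an estimated correlation, adjusted p was 0.894 for the smooth muscle, target, matrix, urothelium and mesenchyme lists; with fry it was 0.199, and 0.387 for urothelium. The cell cycle list passed at 0.0384 with a further quantile normalization. The kidney list reversed to a downward shift at 0.0181 without knockout replicate 1, and its range without 1 mouse was 1.16e-13 to 0.998. The lowest correlation of arrays became 0.982 within and 0.957 between genotypes with the filter on dim genes, which left no gene of the male accessory glands. The causes were not tested. The seed match test was not run, and 20 called genes lay below background in both genotypes.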

Other observations

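The tests of other tissues rising alike and of the Hoxc genes, the covariate fit, the calls kept without 1 mouse as a test of the kidney signal, and the look at the Hox, immunoglobulin and microRNA genes were chosen only after the result was seen. The 4 clusters of Hox genes, which set position along the body axis, differed in direction. Of 6 Hoxc genes above background 5 fell, with log2 differences of -1.25 for Hoxc8, -1.11 for Hoxc5, -0.98 for Hoxc6, -0.93 for Hoxc10 and -0.70 for Hoxc9. The Hoxc median was -0.95 (camera adjusted p = 7.07e-07; adjusted p = 0.344 with an estimated correlation). Hoxd genes had a median of 0.43 with 6 of 6 higher, Hoxb genes 0.40 with 7 of 8 higher and Hoxa genes -0.21 with 7 of 10 lower, and limma passed 0 of these genes, with 14 at an unadjusted p under 0.05. No median of a Hox cluster changed sign under another scaling. Of 6 immunoglobulin genes above background 5 were lower and 3 of them, Igha, Ighm and Igkv8-30, passed. Of 101 microRNA precursors above background, not counting Mir143 and Mir145a, 79 were lower and 22 higher, with a median of -0.23 (camera adjusted p = 0.000213; adjusted p = 0.522 with an estimated correlation). Of these 4 rose, Mir205 by 0.99, Mir99a by 0.91, and, from wild type values below background, Mir200b at least 2.39-fold and Mir181b-1 at least 1.62-fold. Mir375 fell by 0.89, the 1 of these called lower, against 3 when arrays were centred on their medians.

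Adipocyte markers were lower while matrix, urothelium and mesenchyme lists were higher in knockout. Of 26 adipocyte genes outside the fixed list and the named genes, and without Acvr1c, 76.92% were lower, with a median of -0.53. This misses the 80% set beforehand, so less fat in the knockout samples stays open. Any adipocyte genes among the largest falls were thus left out of the 26, which can lower that share. A smaller share of fat might raise other tissues alike. The matrix list exceeded endothelium by 0.60 (SE 0.12), or 4.93 standard errors, and nerve and glia by 27.2, both beyond the bound of 4.30. Mesenchyme passed the bound over nerve and glia (6.67) and not over endothelium (3.82). Urothelium (3.14 and 2.40) and smooth muscle (2.68 and 3.005) passed it over neither. The test cannot decide on less fat, because fat tissue can hold vessels and nerves of its own, which would fall with it. The Hoxc mean was lower by -0.90 and -0.95 in the knockout mice and the adipocyte genes by -0.10 and -0.62, an excess of -2.256 standard errors, within 4.30 but beyond the 2 first set, so less fat cannot be told apart from a change in the Hoxc genes with 2 mice per genotype. Age, hydronephrosis and the deletion itself remain untested candidates.

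Kidney markers were high in wild type replicate 2 and knockout replicate 1. Kidney tissue carried over with these ureters may account for it. Of 23 proximal tubule genes above background on at least 1 array, 95.65% were higher in both of these mice, with medians of 0.43 and 1.43. This was so for 24.4% of all genes, taken without that filter, which can favour genes high on 1 array. Whether the same mice were the source of the genotype calls cannot be decided here. Without knockout replicate 1 the knockout mean of the kidney list was 7.02, below the wild type mean of 7.29. Counts of calls kept without 1 mouse do not help, since such fits take their variance from the genotype left with 2 mice. Limma passed 0 of 44 kidney genes (9 at an unadjusted p under 0.05), but kidney genes varied within each genotype, which makes a call unlikely. With the kidney list mean as a covariate all 459 calls were kept, but that fit called 1969 genes. In it 0 of the 24 largest changes turned sign or shrank to under 50% of their size. The covariate could have moved none of these 24 by more than 19%, so neither count decides the question. Hydronephrosis, which follows genotype, was not tested and does not separate mice of 1 genotype in the labels.

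Dbp and Ciart, outputs of the circadian clock, were 1.61 and 2.10 higher in knockout and did not pass. Both lie outside the fixed lists and the rule for naming, so this pattern was picked from the data. A difference in the hour of collection is a candidate explanation: of 8 genes of the same phase 8 were higher, with a median of 0.79, and Per1 rose by 0.82 (adjusted p = 0.0403) and Per2 by 1.36 (adjusted p = 0.0362). Genes of the opposite phase had a median of -0.3887, with 3 of 4 lower. Knockout replicate 1 lay further along the same course than replicate 2, by 0.56 and -0.32. An effect of genotype or age on the clock was not tested.

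The other pairings of the 4 mice gave at most 0 genes against 459 for genotype. Each of them puts 1 wild type and 1 knockout mouse in both groups, so any difference between the genotypes adds to the variance. A low count was therefore likely beforehand and does not speak for the 459. With 1 of 3 splits as large, the splits are also too few for a share under 0.05.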
